A study of Mus musculus with 12 samples.

How the data were processed

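Messenger RNA was sequenced from the brains of 12 adult C57BL/6 mice, an inbred laboratory strain. The labels place the mice in 3 arms of 4, with 2 females and 2 males in each. Lipopolysaccharide (LPS), a bacterial cell wall component that activates innate immune cells, was injected into the abdominal cavity at 0.5 mg/kg each day for 7 days. The second arm with LPS also received N,N-dimethylacetamide (DMA), an organic solvent used as a drug carrier, whose dose is not given in the sources used here. Control mice received phosphate-buffered saline (PBS), and brains were taken on day 7. Each mouse gave 1 library. The mice are separate animals per the labels.

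The deposited table gives FPKM values (fragments per kilobase of gene, scaled to the fragments of the library) for 56748 genes and 12 libraries, made by the authors from aligned reads. The same table gives another column, the gene length in bases used by the authors, which is not a measurement of a library. Per the submitters' processing notes, the tools named are fastp, HISAT2 2.2.1, featureCounts 2.0.6, DESeq2 1.42.0, edgeR 4.0.16, GATK and STAR, and the genome build is GRCm39. The notes give no role or order for these tools. Gene names, identifiers, biotypes and coordinates were taken from the deposited table, whose build differs from the reference genome available here, so no reference sequence was used. Per the labels' protocols, both a strand-specific and a non-strand-specific library preparation are described, without saying which was used. Genes that overlap on opposite strands, and genes with near-identical copies such as Lyz2 with Lyz1, H2-K1 with H2-D1, and Ifit3 with Ifit3b, are therefore uncertain at the level of single genes. Only columns that name a sample were used, and no other per-sample columns were left aside.

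FPKM multiplied by gene length was a whole multiple of 1 step in every library, within a tolerance of 0.1 reads, for 100% of values of up to 1000 reads. The steps gave read totals of 27.5 M (megareads) in LPS+DMA male replicate 2 to 41.4 M in PBS female replicate 1, with a median of 34.4 M. FPKM times gene length in kilobases summed to between 916956 and 1103280 per library, and the median-of-ratios factor was 1.01 in all libraries, so the deposited FPKM already follow a median-of-ratios scaling rather than a plain total. The recovered reads were used for depth, floors and 2 alternatives chosen after the values had been seen. A floor is the FPKM of 3 reads in a library and covers counting error only. The lowest chi-square per degree of freedom over the 66 pairs of libraries was 24.8, and the log2 correlation between libraries lay between 0.889 and 0.981, so no library appeared to be deposited a second time.

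Tests were run in R 4.3.3 with limma 3.58.1. Genes with FPKM of at least 0.5 in at least 2 of the 12 libraries were kept (19571 genes) and analysed as log2(FPKM + 1), a scale that understates the change of low genes. Treatment comparisons used 1 additive model of sex and treatment over all 12 libraries, with moderated variances that followed the mean expression and were robust to outlying genes. Within-sex comparisons and tests of the difference between sexes used 1 mean per arm and sex. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Gene lists, 40 in all with 706 genes, were fixed before the data were examined, and 39 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The lists cover immune, glial, vascular, neuronal, metabolic, blood and regional brain genes.

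Named genes were chosen by a rule fixed at the same stage. The rule takes up to 10 rising and 10 falling coding genes past the threshold with the largest change and the same direction in both sexes, filled to 5 by the smallest p, up to 3 genes with the smallest p from each list, and a fixed panel of inflammatory and glial genes. Genes without a proper symbol were left out. The text names part of the genes that the rule allows, a part that was reduced after a first count of outlying samples had been seen, and genes named outside the rule are marked as chosen after their values were seen.

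The reversal of the LPS change by DMA was measured as the correlation and covariance, across genes, of the LPS against PBS change and the LPS+DMA against LPS change. Because both use the LPS libraries, those libraries were split into pairs of 1 female and 1 male, and 100 simulated sets without any effect were run in the same way. Alternatives covered the pseudocount, the filter, the scaling, the variance model, the samples and terms in the fit, each library left out in turn, and the list test. Alternatives added after the data were seen were plain per-million scaling, voom on recovered reads, covariates for brain region and for choroid plexus and blood, and leaving out 4 libraries with a cerebellar signal.

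In simulated data with the means and spreads of the 19571 genes, each comparison had 200 changed genes. The noise was drawn independently for each gene, which leaves out variation shared between genes, such as regional content. The shares and false calls below therefore need not hold for these libraries. For LPS against PBS, 16.7% of genes changed by 0.5 on the log2 scale, 62.3% of those changed by 1 and 97.0% of those changed by 2 were recovered, with 6 false calls. For LPS+DMA against LPS the shares were 12.2%, 65.0% and 91.4%, with 2 false calls, and for LPS+DMA against PBS they were 12.3%, 60.3% and 98.6%, with 9 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.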

Results

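Brain RNA was measured in 12 mice, 4 treated with PBS, 4 with LPS and 4 with LPS and DMA, each arm holding 2 females and 2 males. The series' title names an attenuation of LPS-induced neuroinflammation by DMA, so the comparisons were LPS against PBS, LPS+DMA against LPS, and LPS+DMA against PBS. Depth was 36.2 ± 3.92 M recovered reads (M, megareads) in PBS, 33.3 ± 3.92 M in LPS and 32.2 ± 4.18 M in LPS+DMA (SD, n = 4 each). Xist, the RNA that silences an X chromosome, averaged 65.3 FPKM in females and 0.00781 in males, and the Y-linked helicase gene Ddx3y averaged 0 in females and 18.2 in males, so the sex labels matched the libraries. Ribosomal RNA took 0.0389% of reads in LPS female replicate 2 and up to 9.79% in LPS+DMA female replicate 2.

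The libraries differed in which parts of the brain they contained. Gabra6, a GABA receptor subunit of cerebellar granule cells, stood at 74.6 FPKM in PBS female replicate 1, 114 in LPS female replicate 1, 15.6 in LPS male replicate 1 and 90.5 in LPS male replicate 2, and at 0.170 FPKM or less in the other 8 libraries. Ttr, the thyroid hormone carrier made by the choroid plexus, averaged 84.3 ± 162 FPKM in PBS, 1082 ± 660 in LPS and 110 ± 205 in LPS+DMA (SD, n = 4 each). A score of forebrain minus hindbrain content, the mean of the cortex and hippocampus list less that of the cerebellum list, was 0.51 ± 1.56 in PBS, -1.30 ± 2.12 in LPS and 1.91 ± 0.18 in LPS+DMA. The largest principal component held 37.5% of the variance and the next 15.6%. On the first, LPS female replicate 1 and both LPS males lay at 43.2, 49.0 and 52.3, and LPS female replicate 2 at -14.0.

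LPS against PBS asked which brain genes respond to daily LPS. Lyz2, the lysozyme of macrophages and microglia, rose from 8.51 ± 1.60 to 35.0 ± 2.90 FPKM (log2 change 1.93, SE 0.18, adjusted p = 0.00673), with every LPS library above every PBS library. Saa3, an acute-phase serum amyloid gene, rose to 2.35 ± 0.649 FPKM from no reads in any PBS library (adjusted p = 0.0250). Set against a floor of 3 reads per library, Saa3 was at least 75.7-fold higher. Lyz2 is ENSMUSG00000069516 on chromosome 10 from 117113236 to 117118226, and Saa3 is ENSMUSG00000040026 on chromosome 7 from 46361422 to 46365124, both on the minus strand in GRCm39 coordinates of the deposited table. These 2 genes were the calls among 19571 tested, and 2145 genes had an unadjusted p under 0.05.

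Several immune and glial genes had higher means in LPS and did not pass the threshold. H2-K1, a class I antigen presentation gene, was at 21.7 ± 4.19 against 9.48 ± 1.16 FPKM (log2 change 1.10, adjusted p = 0.117). The complement genes C1qa, at 56.9 ± 5.12 against 31.6 ± 3.67 FPKM, and C3, at 1.11 ± 0.228 against 0.297 ± 0.201 FPKM, had adjusted p = 0.117 and 0.161. Isg15, a ubiquitin-like interferon-induced protein, was at 5.17 ± 1.71 against 1.65 ± 0.452 FPKM (adjusted p = 0.127). Gfap, the intermediate filament of astrocytes, was at 91.6 ± 8.53 against 39.2 ± 6.55 FPKM, log2 change 1.21 and adjusted p = 0.181. The iron-binding protein gene Lcn2 was at 1.13 ± 0.509 against 0.0768 ± 0.0486 FPKM (adjusted p = 0.475). Cox8b, Fcgr4 and Ctss gave log2 changes of 1.21, 0.95 and 0.99, with adjusted p = 0.117, 0.117 and 0.180. Among lower genes, the immediate early genes Egr3 and Nr4a1 gave -2.89 (adjusted p = 0.181) and -1.60 (adjusted p = 0.180). Dlk2 gave -1.29, Osbpl3 -0.91 and Smim43 -1.69, at adjusted p = 0.177 to 0.183. In the fixed panel, Serpina3n gave 1.01 (adjusted p = 0.298), C4b 0.79 (0.283), H2-D1 1.22 (0.218), Aif1 0.48 (0.522), Ccl2 0.44 (0.509), Cxcl10 0.19 (0.764), Nfkbia 0.16 (0.887), Tlr4 0.18 (0.621) and Ptgs2 -0.69 (0.311). Tnf, Il1b, Il6 and Nos2 held at most 34 reads in any library and fell below the filter, so they were not tested.

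As groups, 26 of 39 lists ranked higher than other genes in LPS and 4 ranked lower. Other splits of the same 8 libraries into groups of 4 called a median of 16 lists, so the count alone says little. For disease-associated microglia, 1 of 22 tested members passed over all genes and 10 rose adjusted over the list alone, among them Lyz2 and Tyrobp, a microglial signalling adaptor (log2 change 0.73). This list held with an estimated correlation (adjusted p = 0.0152), as did complement, with 0 of 16 members past over all genes and 9 adjusted over the list alone (adjusted p = 0.0313), and MHC class II antigen presentation, with 0 and 1 of 8 (adjusted p = 0.0313). With choroid plexus and blood covariates the mean change of MHC class II went from 0.43 to 0.095 and that of interferon response from 0.42 to 0.21. Interferon response had 33 of 34 members higher, none past over all genes and 12 adjusted over the list alone, with Ifit3 at 0.91 and Bst2 at 0.82 (adjusted p = 0.0607 with an estimated correlation). MHC class I, cytokines and chemokines, and endothelial cells and tight junctions each lost their call as well (adjusted p = 0.0672 with an estimated correlation), including the drug efflux pump gene Abcb1a at 0.58. Reactive astrocytes ranked higher too (adjusted p = 0.0699 with an estimated correlation).

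Markers of other tissue moved with the LPS arm beside these immune lists. All 20 tested choroid plexus genes were higher, with Kl at 1.55 (list adjusted p = 0.0699 with an estimated correlation), and red blood cell genes had a median change of 1.35, with Alas2 at 1.94 (adjusted p = 0.0672 with an estimated correlation). Neutrophil genes ranked higher, with S100a9 at 2.69 (adjusted p = 0.121 with an estimated correlation), as did cerebellum genes, with Gabra6 at 2.79 (adjusted p = 0.472 with an estimated correlation), while cortex and hippocampus genes ranked lower, with Tbr1 at -2.19 (adjusted p = 0.213 with an estimated correlation). Synapse and immediate early gene lists ranked lower with 9 and 11 members adjusted over the list alone, and lost their calls (adjusted p = 0.167 and 0.121 with an estimated correlation). With the forebrain-hindbrain covariate their mean changes went from -0.60 to -0.34 and from -0.88 to -0.55. With choroid plexus and blood covariates these 2 means were -0.19 and -0.41. The mean change of cerebellum turned from 1.12 to -0.34 with the forebrain-hindbrain covariate. Olfactory bulb genes ranked lower as well (adjusted p = 0.391 with an estimated correlation). The other 14 lists ranking higher had adjusted p between 0.135 and 0.592 with an estimated correlation: LPS sensing and NF-kB targets, homeostatic microglia, perivascular and border macrophages, astrocytes, endothelial activation, pericytes and smooth muscle, fibroblasts and meninges, myelin, oxidative stress response, mitochondrially encoded genes, nuclear oxidative phosphorylation, cytosolic ribosomal proteins, cholesterol synthesis and ependymal cells. With choroid plexus and blood covariates the mean change turned for myelin (0.55 to -0.75), ependymal cells (0.32 to -0.59), pericytes (0.19 to -0.062), astrocytes (0.17 to -0.012), homeostatic microglia (0.14 to -0.043), cholesterol synthesis (0.11 to -0.0015) and olfactory bulb (-0.65 to 0.36). Homeostatic microglia lost its call without any library other than PBS female replicate 2, either PBS male, LPS female replicate 1 or LPS+DMA male replicate 1 (adjusted p = 0.0536 to 0.663). Astrocytes and cerebellum lost theirs without PBS female replicate 2, LPS female replicate 1 or LPS male replicate 2 (0.0637 to 0.264), and astrocytes also without PBS male replicate 2 (0.0535). Ribosomal proteins and cholesterol synthesis lost theirs without PBS female replicate 1 or LPS female replicate 2 (0.0530 to 0.138). Ependymal cells did so without any PBS or LPS female or LPS male replicate 1 (0.0623 to 0.310). The calls of pericytes (0.0770), perivascular macrophages (0.0583) and cholesterol synthesis (0.0592) were lost without LPS male replicate 1, that of pericytes without PBS male replicate 1 (0.0631) and that of olfactory bulb without PBS female replicate 2 (0.348). The lists of inflammasome, neurons, oligodendrocyte precursors, glucocorticoid response, unfolded protein and heat shock response, monocytes and T cells, striatum, hypothalamus and thalamus did not pass, and pituitary had 4 tested members and was not tested.

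Lyz2 lost its call without PBS female replicate 2, LPS female replicate 1 or LPS male replicate 1 (adjusted p = 0.0542, 0.0575 and 0.0603), and Saa3 lost it without any library other than LPS female replicate 2, LPS male replicate 2 or LPS+DMA male replicate 1 (adjusted p = 0.0532 to 0.174). Without LPS female replicate 2, 672 genes were called, 485 of them lower in LPS. This LPS library had forebrain content and also the lowest share of ribosomal RNA, 0.0389% of reads, and the 2 cannot be told apart. With choroid plexus and blood covariates limma called 0 (706 at an unadjusted p under 0.05).

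LPS+DMA against LPS asked which of these genes DMA moves. Lyz2 fell from 35.0 ± 2.90 to 6.73 ± 1.99 FPKM (log2 change -2.25, SE 0.18, adjusted p = 0.00103) and Tyrobp from 25.7 ± 2.22 to 10.5 ± 1.83 FPKM (-1.23, SE 0.13, adjusted p = 0.00436). Saa3 fell to 0.202 ± 0.365 FPKM (-1.50, adjusted p = 0.0172, a call lost without LPS female replicate 1 or LPS male replicate 1 at adjusted p = 0.0651 and 0.0764), Isg15 to 1.34 ± 0.274 FPKM (-1.37, adjusted p = 0.0172) and Gfap to 38.2 ± 16.9 FPKM (-1.34, adjusted p = 0.0203). Camk2a, a synaptic kinase of neurons, rose from 90.4 ± 135 to 317 ± 22.9 FPKM (3.11, adjusted p = 0.0270). In all, 1892 of 19571 genes passed, 1133 higher and 759 lower in LPS+DMA, and 1694 of them code for proteins. With the forebrain-hindbrain score as a covariate 2 genes passed, Lyz2 and Tyrobp (1850 at an unadjusted p under 0.05). With choroid plexus and blood covariates limma called 0 (640 unadjusted). In that fit the median absolute change of the 1892 genes went from 0.76 to 0.51 and its SE from 0.18 to 0.29. Of these genes 99.5% kept their direction, so 0 calls came from a smaller change and a larger SE together. With no filter 83 passed.

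Part of the antigen presentation, interferon and complement genes fell. In the interferon response 15 of 34 tested members fell over all genes and 23 adjusted over the list alone, with Bst2 at -1.10 and Isg15 at -1.37 (list adjusted p = 0.117 with an estimated correlation). In MHC class II antigen presentation 5 of 8 fell, with 7 adjusted over the list alone: the protease gene Ctss went from 87.6 ± 2.79 to 29.0 ± 10.5 FPKM and the invariant chain gene Cd74 from 4.58 ± 1.61 to 0.824 ± 0.660 FPKM. This list held with an estimated correlation (adjusted p = 0.0458). In complement 8 of 16 fell, 10 adjusted over the list alone, with C1qa at -0.79, C3 at -0.78 and C4b going from 9.18 ± 1.84 to 4.19 ± 1.40 FPKM (adjusted p = 0.147 with an estimated correlation). MHC class I had 5 of 13 falling, among them H2-K1 and H2-D1 at -1.08 and -1.05 (adjusted p = 0.241 with an estimated correlation), and disease-associated microglia 12 falling and 1 rising of 22 (adjusted p = 0.0992 with an estimated correlation). Homeostatic microglia had 4 falling and 1 rising of 17, with Aif1 at -0.92 (list adjusted p = 0.419 with an estimated correlation). Aif1 passed the threshold in 9 of 30 settings, and LPS+DMA male replicate 1 had a homeostatic score of 2.05 against an arm mean of 2.81. The list of reactive astrocytes had 6 falling of 28 (adjusted p = 0.241 with an estimated correlation). In the cytokine list Ccl5 fell by 1.18 on the log2 scale and Cx3cl1, a neuronal chemokine, rose by 1.54. Of the panel, Ptgs2, a prostaglandin synthase gene, rose (0.76, adjusted p = 0.0399), and Serpina3n (-0.65, adjusted p = 0.160), Lcn2 (0.48, 0.517), Nfkbia (0.25, 0.635), Tlr4 (-0.19, 0.333), Cxcl10 (-0.43, 0.193) and Ccl2 (-0.36, 0.317) did not pass. Ptgs2 passed the threshold in 13 of 30 settings, with a change as low as 0.096. Its LPS libraries spanned 0.368 to 2.81 FPKM and overlapped the 1.93 to 3.23 FPKM of LPS+DMA.

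The rising genes included Ddn (4.16), Kcnj4 (3.76), Nrgn (3.50), Ptk2b (3.30), Lrrc10b (3.02), Icam5 (2.97) and Kcnh3 (2.82), with adjusted p between 0.0203 and 0.0432. The falling genes were led by Ttr (-5.62), the glycine transporter gene Slc6a5 (-3.56), Sncg (-3.01), Klk6 (-2.99), Ecrg4 (-2.67), Kcng4 (-2.61), the glycine receptor gene Glra1 (-2.60), Pvalb (-2.43), Rln3 (-2.43) and Spp1 (-2.39), with adjusted p between 0.0197 and 0.0479. Over 30 settings, 1 of which left 1 LPS library, these changes could shrink strongly. The weakest ran from -0.00057 (Nrgn) to 0.97 (Kcnj4) for these rising genes, and from 0.17 (Rln3) to -1.54 (Klk6) for the falling ones. In the synapse list 16 of 24 rose, with Homer1 at 1.78, and in the immediate early list 9 of 23, with Egr3 at 2.82 and Nr4a1 at 1.75 (adjusted p = 0.241 with an estimated correlation for both lists). In the cortex and hippocampus list 7 of 17 rose, with Tbr1 at 2.71 and Bcl11b at 2.45 (adjusted p = 0.241 with an estimated correlation). In choroid plexus 14 of 20 fell, with Enpp2 at -1.85 (adjusted p = 0.241 with an estimated correlation), and cerebellum and striatum had opposite medians of -1.94 and 1.43 (adjusted p = 0.419 with an estimated correlation for both). In cholesterol synthesis 11 of 19 fell, with Sc5d at -0.73 and Idi1 at -0.79 (adjusted p = 0.156 with an estimated correlation), and in the myelin list 2 of 17 fell (adjusted p = 0.417 with an estimated correlation). Overall 24 of 39 lists passed, 18 lower and 6 higher, the others among them being cytokines, astrocytes, endothelial cells and tight junctions, oxidative stress response, nuclear oxidative phosphorylation, red blood cells, ependymal cells, glucocorticoid response and olfactory bulb (adjusted p = 0.241 to 0.627 with an estimated correlation). Other splits of the same 8 libraries called a median of 14.5 lists. With choroid plexus and blood covariates the mean change turned for ependymal cells (-0.52 to 0.21) and olfactory bulb (0.76 to -0.064). It went from 0.43 to 0.043 for glucocorticoid response, from -1.04 to -0.20 for myelin and from -0.44 to -0.24 for MHC class I. With the forebrain-hindbrain covariate the mean change went from 0.89 to 0.44 for synapse and from 1.02 to 0.43 for immediate early genes. It went from -0.41 to -0.11 for astrocytes and from -0.61 to -0.42 for interferon response. That of cerebellum, a list that is part of this score, turned from -2.09 to 0.51. The glucocorticoid call was lost without LPS+DMA male replicate 1 (adjusted p = 0.814), PBS female replicate 1, LPS female replicate 2, LPS+DMA female replicate 2, PBS male replicate 1 or LPS male replicate 1 (0.0519 to 0.206). Ependymal cells and olfactory bulb lost theirs without either LPS female or LPS+DMA male replicate 1 (0.0517 to 0.220), and olfactory bulb also without LPS+DMA female replicate 1 (0.118). Cytokines and endothelial cells lost theirs without LPS female replicate 2 or LPS+DMA female replicate 1 (0.0533 to 0.154), cytokines also without LPS+DMA male replicate 2 (0.0835), and endothelial cells without LPS or LPS+DMA male replicate 1 (0.0653 and 0.0577). The lists that did not pass were LPS sensing and NF-kB targets, inflammasome, perivascular macrophages, endothelial activation, pericytes, fibroblasts, neurons, oligodendrocyte precursors, unfolded protein response, mitochondrially encoded genes, ribosomal proteins, neutrophils, monocytes and T cells, hypothalamus and thalamus.

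Without LPS female replicate 1, LPS male replicate 1 or LPS male replicate 2, the LPS libraries with cerebellar signal, 11, 7 and 22 genes were called, and 3465 without LPS female replicate 2. Left out in turn, LPS+DMA female replicates 1 and 2, LPS+DMA male replicate 2 and PBS male replicates 1 and 2 gave 1228, 1071, 1119, 1166 and 1052, and a fit of these arms alone gave 5. Plain per-million scaling, which moved the median of all genes by -0.11, called 2861 genes with 580 higher and 2281 lower, and scaling to protein-coding genes, which moved it by -0.13, called 2926 with 809 higher and 2117 lower.

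**Figure D1:**
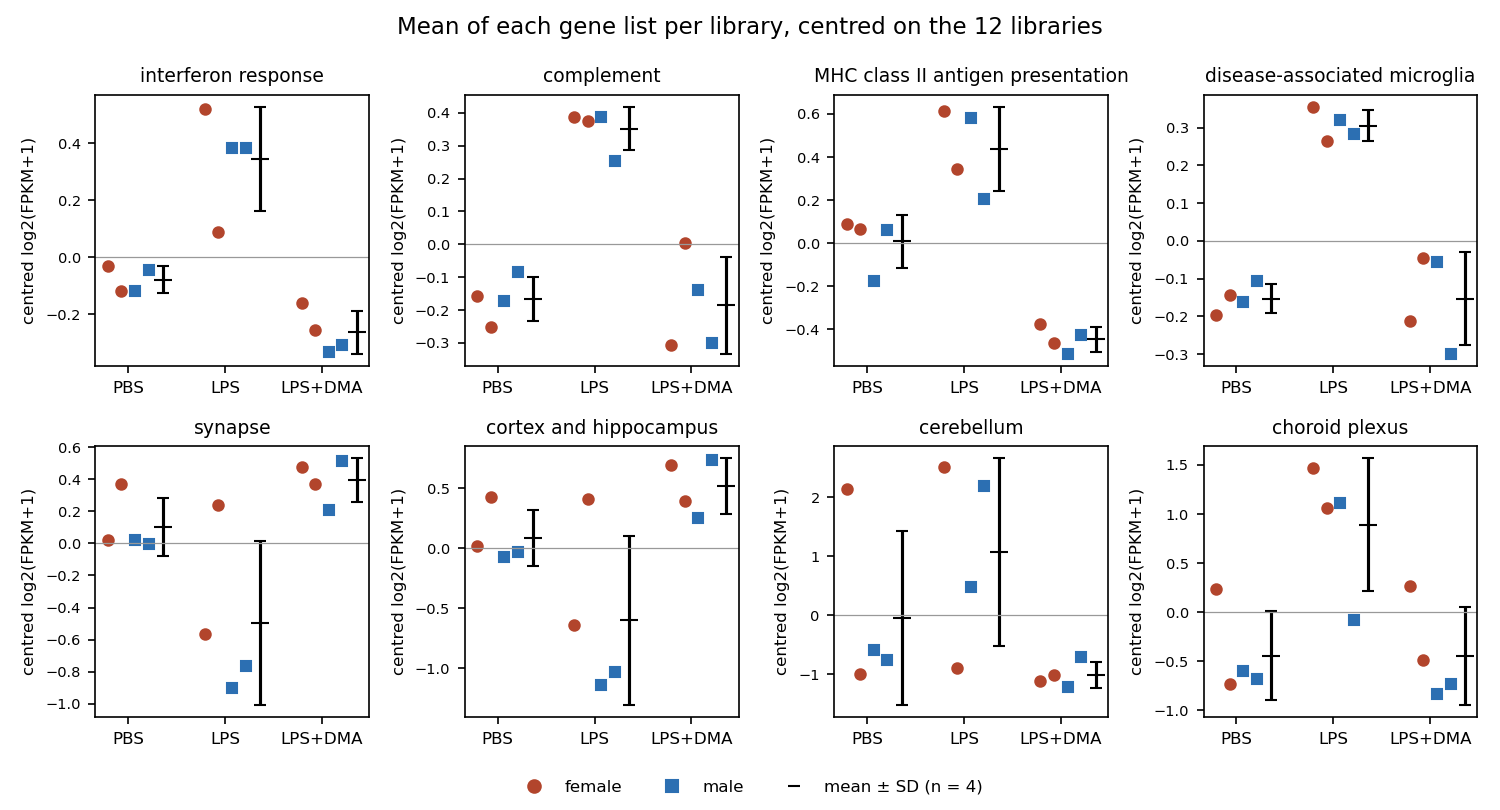
Mean log2(FPKM + 1) of 8 gene lists in each library, centred on the 12 libraries (y axis, log2 units), by treatment arm, with the arm mean ± SD (n = 4). The interferon response score averaged 1.84 in LPS and 1.24 in LPS+DMA before centring, and the cerebellum score had an SD of 1.59 within LPS.

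LPS+DMA against PBS asked which genes differed from controls after both treatments. Chil1, a chitinase-like protein of glia and immune cells, fell from 4.04 ± 0.972 to 1.82 ± 0.655 FPKM (log2 change -0.84, SE 0.10, adjusted p = 0.0269), with every LPS+DMA library below every PBS library. ENSMUSG00002075017, an unnamed short RNA gene chosen after its values were seen, fell from 7.92 ± 3.25 to 0.494 ± 0.228 FPKM (-2.51, SE 0.28, adjusted p = 0.0269). These 2 were the calls, and 2235 genes had an unadjusted p under 0.05. Lyz2 and Saa3 did not belong to the calls. Smim40 (1.41, adjusted p = 0.110), Abcb1a (0.53, 0.236), Macrod2 (0.59, 0.284), Strn (0.78, 0.290), Nrbp2 (-0.72, 0.110), Gsta4 (-0.62, 0.173), Wsb1 (-0.78, 0.284) and Cd74 (-1.18, 0.324) had the next smallest p or were list members, and Lcn2 was at 2.67 ± 2.62 against 0.0768 ± 0.0486 FPKM (1.44, adjusted p = 0.344). Of 39 lists 19 passed, 10 higher and 9 lower, and none held with an estimated correlation, the lowest adjusted p being 0.218 for MHC class II. Other splits of the same 8 libraries called a median of 13 lists. The lists lower were interferon response, MHC class II, homeostatic microglia, astrocytes, myelin, nuclear oxidative phosphorylation, cholesterol synthesis with Sc5d at -0.52, cerebellum and thalamus, and those higher were endothelial cells, endothelial activation, synapse, glucocorticoid response, mitochondrially encoded genes, red blood cells, neutrophils, striatum, cortex and hippocampus, and cytosolic ribosomal proteins, whose mean of 0.12 turned to -0.030 with plain per-million scaling. No member of these lists passed over all genes, and 8 cholesterol synthesis genes and 3 MHC class II genes fell adjusted over the list alone. With the forebrain-hindbrain covariate the mean change of cerebellum turned from -0.97 to 0.17. Those of synapse and of cortex and hippocampus went from 0.29 to 0.092 and from 0.43 to 0.17. Without LPS+DMA male replicate 1 the calls of homeostatic microglia, astrocytes, myelin, endothelial activation, glucocorticoid response and ribosomal proteins were lost (adjusted p = 0.0703 to 0.860). Without LPS+DMA male replicate 2 those of nuclear oxidative phosphorylation, synapse, neutrophils, and cortex and hippocampus were lost (0.0550 to 0.640). The calls of endothelial cells, red blood cells and ribosomal proteins were lost without LPS+DMA female replicate 2 (0.0755 to 0.110), that of astrocytes without LPS+DMA female replicate 1 (0.124), and those of astrocytes, ribosomal proteins and cerebellum without PBS female replicate 1 (0.111 to 0.439). Chil1 passed without LPS female replicate 1 or 2 and lost its call without any other library (adjusted p = 0.0604 to 0.213). With either covariate fit limma called 0 genes (1703 and 4166 at an unadjusted p under 0.05).

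The direction of the DMA change across genes was opposite to that of LPS. With LPS libraries split so that no library served both changes, the 19571 genes gave r = -0.53 (range -0.65 to -0.42 over splits) between the LPS and DMA changes, and a covariance of -0.0925, against -0.000155 in simulated sets without any effect. These are correlations across genes, which are not independent replicates. With the libraries unsplit, r was -0.78, against -0.50 in the simulated sets. The simulated sets leave out the regional content of the libraries, whose mean forebrain-hindbrain scores in PBS, LPS and LPS+DMA (0.51, -1.30 and 1.91) also went in opposite directions. The correlation between the LPS and LPS+DMA changes from PBS was -0.24 with PBS libraries split (range -0.45 to -0.0283).

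Both genes called higher in LPS, Lyz2 and Saa3, were among the 759 genes lower in LPS+DMA, against 0.0776 from independent lists, and as both comparisons use the LPS libraries part of the excess can come from those libraries.

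Sex differences were 7 genes, 4 higher in males, all Y-linked (Ddx3y, Eif2s3y, Kdm5d and Uty), and 3 higher in females (Xist, Tsix and ENSMUSG00002075094), all but Xist and Ddx3y named after their values were seen. No gene passed a test of the difference between sexes in any treatment comparison (limma, 0 genes), with 491, 1008 and 1110 genes at an unadjusted p under 0.05 for LPS against PBS, LPS+DMA against LPS and LPS+DMA against PBS. Within sexes, LPS against PBS called 0 genes in females and 0 in males (915 and 1628 at an unadjusted p under 0.05), and LPS+DMA against LPS 0 in females (1686 unadjusted) and 1009 in males. These counts do not compare the sexes, whose own test called 0 genes as given above. The male count was 0 without any one of the PBS or LPS males, 4 without either LPS+DMA female, 403 and 401 without PBS female replicates 1 and 2, 612 without LPS+DMA male replicate 1 and 4889 without LPS+DMA male replicate 2. Without LPS+DMA male replicate 2, replicate 1 is the only LPS+DMA male left. That mouse stood apart, with a glucocorticoid score of 4.66 against 2.98 to 3.71 in the other 11 libraries. The male count and the tests of the difference between sexes then rest on 1 outlying mouse, so they do not measure a sex difference.

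**Figure D2:**
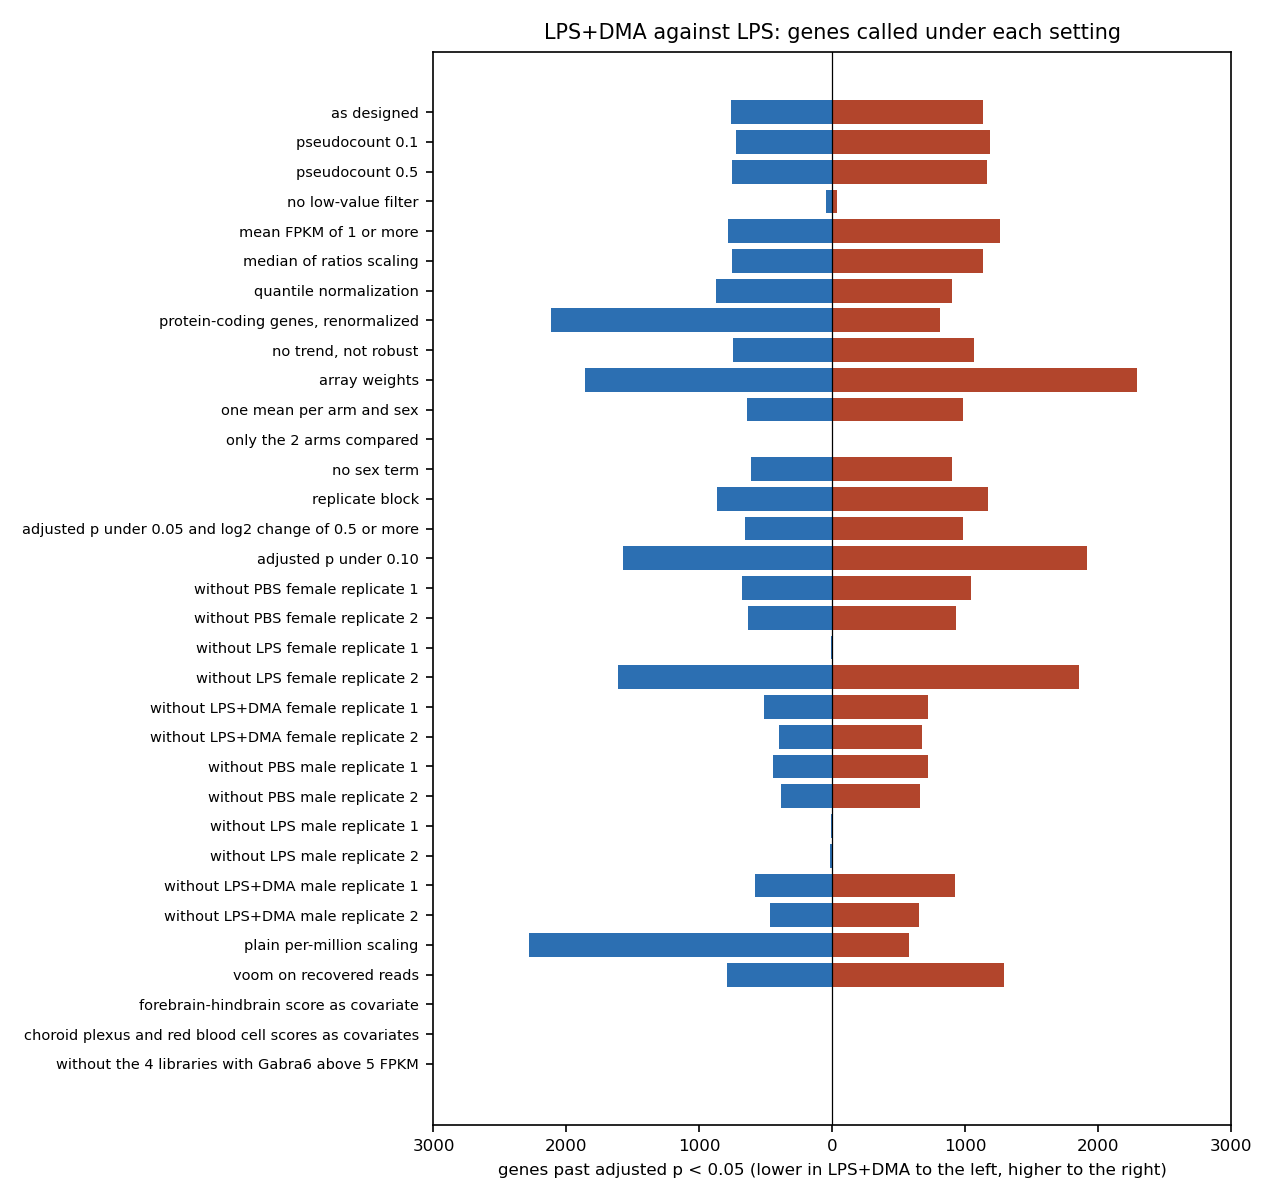
Number of genes past the threshold in LPS+DMA against LPS under each setting (x axis, genes; lower in LPS+DMA to the left, higher to the right), one bar per setting. The design gives 1892 genes, and settings with covariates for brain region or for choroid plexus and blood give 2 or fewer. The bar without the libraries with Gabra6 above 5 FPKM rests on 1 LPS library.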

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

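The samples below lay far from the other 3 of their arm, and the tests of LPS+DMA male replicate 1 were chosen after its values were seen. They are given for genes and lists the text names, where 36 of 333 groups of 4 held such a sample. Over every gene the naming rule takes the share was 81 of 819, or 9.89%, and chance gives about 1 in 20.

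PBS female replicate 2 was high in Cx3cl1 at 158 FPKM, Egr3 at 30.7, Fcgr4 at 0.345, Icam5 at 58.0, Kcnj4 at 56.7, Osbpl3 at 5.05, Ptk2b at 55.7 and Tlr4 at 0.576, and low in Sncg at 2.42 FPKM. Its scores were 5.25 for the synapse list, 6.45 for nuclear oxidative phosphorylation and 3.82 for olfactory bulb. PBS female replicate 1 was high in Gabra6 at 74.6 FPKM, Kl at 1.78 FPKM, the choroid plexus list at 1.83 and the cerebellum list at 4.93. PBS male replicate 1 was low in the MHC class II list at 1.44 and the endothelial activation list at 1.12.

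LPS female replicate 2 was high in Dlk2 at 5.13 FPKM, Macrod2 at 5.70 and Smim43 at 3.42, and low in Klk6 at 3.48 FPKM. Its scores were 3.65 for homeostatic microglia, 3.99 for striatum and 3.81 for hypothalamus, and mitochondrial ribosomal RNA took 0.0111% of its reads. LPS male replicate 2 was low in the complement list at 2.71.

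LPS+DMA female replicate 1 was low in C4b at 2.13 FPKM and S100a9 at 2.02 FPKM. LPS+DMA male replicate 2 was high in Gabra6 at 0.170 FPKM, Rln3 at 0.970 and Slc6a5 at 0.832, and low in nuclear oxidative phosphorylation at 5.73. LPS+DMA male replicate 1 was high in the chemokine genes Ccl2 at 0.778 FPKM and Cxcl10 at 0.474 and in Saa3 at 0.750.

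LPS+DMA male replicate 1 also stood at 4.66 in the glucocorticoid response list, against 2.98 to 3.71 in the other 11 libraries, at 3.46 in the myelin list and at 2.05 in homeostatic microglia. Its glucocorticoid score lay 5.83 standard errors from that predicted by the forebrain-hindbrain score of the other libraries. The bound for 95% of predictions is 2.26, but it holds for a library not chosen for its score, so this test cannot decide. The forebrain-hindbrain score of this library, 1.85, lay within the 1.78 to 2.18 of its arm, so this axis did not set it apart. Its 33.7 M reads (megareads) lay within the range of the other libraries, which argues against depth. Handling, stress and tissue sampling of this mouse stay open, and no biological explanation was tested because the labels give this mouse no group of its own.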

How the results depend on the processing

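Settings named as plain scaling, voom, covariates and libraries without Gabra6 were chosen after the data were seen, and for each change below the cause was not tested unless fewer samples or genes show it. For single named genes, 2316 values kept direction and side of the threshold, 457 lost and 54 gained a call, and 9 turned. The turned values were Nfkbia in LPS+DMA against LPS without LPS+DMA male replicate 1 (-0.16, the range without single libraries being -0.16 to 0.57) and with choroid plexus and blood covariates (-0.23), Gabra6 in LPS against PBS with the forebrain-hindbrain covariate (-0.22), and, with choroid plexus and blood covariates, Kl (-0.0087), Lcn2 (-0.11) and Enpp2 (0.051). Without the 4 libraries with Gabra6 above 5 FPKM, 1 LPS library is left, LPS female replicate 2, so every LPS value given here for that setting compares 1 mouse with the other arm and says little of the LPS arm. There they were Cxcl10 (-0.068), Nrgn (-0.00057) and Rln3 (0.17).

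For LPS against PBS (2 genes), 1 gene was called with a pseudocount of 0.1, with no filter, with mean FPKM of 1 or more, with the forebrain-hindbrain covariate and with voom, 5 with protein-coding scaling, 2852 with array weights, 4 with these arms alone, 0 with choroid plexus and blood covariates and 4, none shared, without the Gabra6 libraries. For LPS+DMA against LPS (1892) the counts were 83 with no filter, 2926 with protein-coding scaling, 4152 with array weights, 5 with these arms alone, 3489 at an adjusted p under 0.10, 2861 with plain scaling, 2 with the forebrain-hindbrain covariate, 0 with choroid plexus and blood covariates and 5, none shared, without the Gabra6 libraries. For LPS+DMA against PBS (2) they were 0 with no filter, these arms alone, no sex term, voom, either covariate fit and without the Gabra6 libraries, and 1 with protein-coding scaling and with 1 mean per arm and sex. Sex genes (7) were 4 with protein-coding scaling and 14 with array weights. With no filter the sex difference of LPS against PBS called 2 genes.

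Within sexes, LPS against PBS called 6 genes in females and 16 in males with no filter, 2 in males with neither trend nor robust variances and 618 in males with array weights. LPS+DMA against LPS called in females 3 with no filter, 5 with protein-coding scaling, 5 with array weights, 4 at an adjusted p under 0.10 and 4 with plain scaling. In males (1009) it called 50 with no filter, 1805 with protein-coding scaling, 0 with array weights, these arms alone or either covariate fit, and 2624 at an adjusted p under 0.10.

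The deviations of same-numbered samples from the mean of their arm and sex were correlated between 2 arms. The values lay between -0.0705 and 0.452, above 0.1 in 2 of 6 pairs, the highest being PBS and LPS females. With 2 samples per arm and sex that differ in regional content, this cannot show whether replicate numbers pair the samples. With the replicate block 1 gene was called for LPS against PBS, 1 for LPS+DMA against PBS and 1 for LPS against PBS in males. Median-of-ratios scaling moved nothing, and within-sex fits without the Gabra6 libraries were not possible with 1 LPS library left.

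Leaving out each library gave 0 to 672 genes for LPS against PBS, 7 to 3465 for LPS+DMA against LPS, 0 to 6 for LPS+DMA against PBS and 5 to 9 for sex. The differences between sexes gave 0 to 17, 0 to 786 and 0 to 952. Within sexes LPS against PBS gave 0 to 5 in females and 0 to 108 in males, and LPS+DMA against LPS 0 to 122 and 0 to 4889. Where 1 library was left in an arm and sex, it was assumed to vary like the others, and such counts rest on 1 mouse. The highest counts for sex differences with LPS+DMA, and for LPS+DMA against LPS in males, rested on LPS+DMA male replicate 1, which stood apart.

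Lists past the threshold numbered 25 to 31, 19 to 27 and 13 to 22 without single libraries, against 30, 24 and 19. They were 3, 1 and 0 with an estimated correlation and 15, 13 and 2 with fry. LPS against PBS had 11 with choroid plexus and blood covariates and 18 without the Gabra6 libraries, and LPS+DMA against PBS 12 with the forebrain-hindbrain covariate. Median, mean and test differed in sign for lists that did not pass, such as unfolded protein response in LPS against PBS. The correlation of the LPS and DMA changes was -0.78 unsplit and -0.68 over genes with mean FPKM of 5 or more, against -0.53. Tnf and Il6 fell below the filter and were not tested.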

Other observations

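The tests by covariate and by splits were set down before their results were seen, except that 4 patterns of immune lists were afterwards renamed and merged to 1 with their bounds kept. Splits with balanced sexes were counted after the results of all splits were seen, and the covariates themselves were chosen after the data were seen. Striatal genes, all 13 of them, had higher means in LPS+DMA than in PBS, with a median log2 change of 1.53 and 9 higher adjusted over the list alone (adjusted p = 0.623 with an estimated correlation). The medians were 2.84 in females and 0.44 in males, a difference that was not tested. Mitochondrially encoded genes had 12 of 13 higher in the same comparison, 3 adjusted over the list alone (adjusted p = 0.623 with an estimated correlation), and cholesterol synthesis genes 18 of 19 lower, 8 adjusted over the list alone (adjusted p = 0.271 with an estimated correlation). Myelin genes were lower in LPS+DMA than in LPS by medians of -0.52 in females and -1.90 in males (adjusted p = 0.417 with an estimated correlation). With choroid plexus and blood covariates their mean change over both sexes went from -1.04 to -0.20. The sexes were not compared by a test, and among the LPS+DMA males replicate 1 had a myelin score of 3.46 and replicate 2 of 5.12.

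The 1892 genes that differed between LPS+DMA and LPS included 7 of 17 cortex and hippocampus genes and 0 of 14 cerebellum genes, the latter with a median log2 change of -1.94. With the forebrain-hindbrain score as a covariate the median ratio of adjusted to unadjusted change was 0.634 (0.563 to 0.777 without single libraries). A ratio of 0.2 or less was set for a regional cause and 0.5 or more, as here, against it. The cortex and hippocampus list, part of the score, itself kept a ratio of 0.456, so the test cannot decide on this axis. The median absolute change went from 0.76 to 0.48, its SE from 0.18 to 0.21, and 2 calls were left, Lyz2 (-2.34) and Tyrobp (-1.43), both at adjusted p = 0.0358. Regional content on this and other axes and DMA treatment stay open, and part of the change may follow tissue sampling. Of 35 splits of the 8 libraries, 1 gave as many genes, the real one, and the highest other gave 452. That other split also kept the 3 LPS libraries with Gabra6 above 5 FPKM together. The share of 1 of 35 was under 0.05 but is the lowest that 35 splits can give. It makes chance less likely without excluding it. Of the 18 splits with 2 females in each group the real one was also highest (highest other 1). Those 18 are too few for a share under 0.05. The count was 11, 7 and 22 without LPS female replicate 1, LPS male replicate 1 and LPS male replicate 2, 3465 without LPS female replicate 2, and 1052 to 1228 without either PBS male, either LPS+DMA female or LPS+DMA male replicate 2. For the lists (24), 4 of 35 gave as many, the highest other gave 30 and the median other 14.5, so chance is not excluded.

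Immune gene lists had higher means in LPS than in PBS and LPS+DMA. With the forebrain-hindbrain score as a covariate the median ratio over these lists was 0.984 for LPS+DMA against LPS and 0.991 for LPS against PBS. The lists were cytokines and chemokines, LPS sensing and NF-kB targets, interferon response, MHC class I and II, complement, and disease-associated microglia. For LPS+DMA against LPS their ratios ran from 0.691 for interferon response and 0.720 for MHC class I to 1.45 for cytokines and chemokines. Each lay above the 0.456 that the cortex and hippocampus list, part of the score, kept. This argues against regional content on this axis as the whole cause for the lists as a set, and not for interferon response or MHC class I alone. The cytokine list includes Cx3cl1, which rose, so its ratio mixes opposite changes. Reactive astrocytes and neutrophils, outside this set, had ratios of 0.565 and -0.030, so a part by region stays open. With choroid plexus and red blood cell scores the median ratio was 0.933 for LPS+DMA against LPS (0.754 to 1.16). The ratios were 0.534 for MHC class I, 0.683 for MHC class II and 0.740 for interferon response, and 0.933 to 1.30 for the other lists. This argues against such RNA as the whole cause for the lists as a set, and not for those 3 lists alone. For LPS against PBS the median ratio was 0.887, and 0.416 without LPS+DMA male replicate 1. The mean of MHC class II went from 0.43 to 0.095 (ratio 0.222). Choroid plexus and blood RNA therefore cannot be told apart from the LPS change there. An LPS response that DMA lowers may remain as a hypothesis, as may immune cells in blood or meninges.

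For LPS against PBS, 2 of 35 splits gave as many genes as the real 2, and the highest other gave 1218, the split that sets the 4 libraries with Gabra6 above 5 FPKM against the rest, which points to a structure of the samples. Chance is not excluded for this count of genes, which is no test of Lyz2 alone. For the lists the real split gave 30, the highest other 28 and the median other 16 (1 of 35 as high as the real one). That share is under 0.05 but the lowest that 35 splits can give, so chance is less likely and not excluded. With an estimated correlation 3 of these lists held. The 18 splits with balanced sexes also had 28 as the highest other and are too few for a share under 0.05. For LPS+DMA against PBS, 2 of 35 splits gave as many genes (highest other 10) and 2 of 35 as many lists (19, highest other 20, median other 13), so chance is not excluded. For sex, 2 of 100 splits gave as many genes as the real 7, the highest other giving 11.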
